A study of Mus musculus with 11 samples.

How the data were processed

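SLAM-seq libraries of mouse ESC, EpiLC and PGCLC were described in the labels of the series, with 3 replicates for each cell type treated with iodoacetamide and 2 libraries without it. According to the labels, ES cells were grown in 2i and LIF, EpiLC were induced for 2 days and PGCLC for 4 days, and PGCLC were sorted on ITGB3 and SSEA1. Per the labels, RNA was labelled with 400 µM s4U for 1 h and sequenced as QuantSeq 3′ libraries on a HiSeq instrument. The labels do not say whether replicates with the same number came from 1 culture.

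The authors deposited 1 table of read counts per 3′ UTR interval of GRCm38/mm10, with 90751 rows and, for every library, a steady-state and a transcription column. These count columns were taken as deposited. The transcription count was read as the number of reads with T-to-C changes, since it never exceeded the steady-state count and was lowest in the libraries without iodoacetamide. The authors' processing notes name limma 3.42.2, while the tools that aligned the reads and called conversions are not given in the sources used here.

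Of 55640 transcript identifiers in the table, 55084 were found in GENCODE release M21, which left 849 rows without a gene name. These rows held between 0.611% and 0.700% of the reads of a library and were left out. Many rows of a gene overlap, and adding them would count a read more than once, so the largest set of non-overlapping intervals of each gene was kept, 53090 rows for 21770 gene symbols. In 31 cases a symbol stood for more than 1 gene identifier, and 368 genes had over 10% of their reads in an interval shared with another gene. Counts per 1000000 reads (CPM) were computed with library sizes scaled by TMM factors. A group with 0 reads was given a floor of 3 reads, and intervals on ratios with 1 to 3 reads cover counting error only at 95%.

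Differences between cell types were tested for 3 quantities: total counts, labelled counts, and the labelled to unlabelled ratio, here called labelled share. Each was fitted over the 9 treated libraries at once in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr), with contrasts EpiLC minus ESC, PGCLC minus EpiLC and PGCLC minus ESC. The share model had a term for each library and separate TMM factors for labelled and unlabelled counts, so that its values are relative to the typical gene of the library. The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The overall labelled share of a library was compared by an exact permutation test. The 2 libraries without iodoacetamide served as single values of background.

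A total of 24 gene lists with 334 members, of which 327 were found, had been fixed before the data were examined. They covered naive pluripotency, shared pluripotency, formative epiblast, PGC specification, later germline and meiosis, mesoderm, BMP-SMAD targets, endoderm, trophoblast, neurectoderm, 2-cell-like genes, and the DNA methylation machinery. The others were deadenylation, decapping and 5′ decay, the exosome, NMD factors, NMD-sensitive transcripts, immediate-early and dissociation stress genes, p53 targets, glycolysis, cholesterol synthesis, proliferation, nuclear oxidative phosphorylation, and ribosomal proteins. Lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01 and with an estimated correlation, adjusted over all lists of 1 contrast.

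Genes were named by a rule fixed beforehand. It took 18 marker genes and up to 4 members of each list with the lowest adjusted p. For total counts it added the 6 highest and 6 lowest log2 differences among genes that passed, were separated in all replicates and reached 10 CPM in the higher group. Symbols of predicted genes, ribosomal proteins and mitochondrial genes were left out of that part. For labelled counts it added 4 highest and 4 lowest in the same way, and for labelled share 6 highest and 6 lowest among genes with at least 20 labelled reads in every library of a group. Some genes that the rule selects are not reported here.

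Alternatives for the counts were RLE size factors, no filter, a stricter filter, a replicate block, only the 2 groups compared, a change of at least 2-fold, DESeq2 1.42.0, limma voom, and omission of each library. For labelled reads and share they also included the library sizes of the total reads, limma on median-centred log2 ratios, and subtraction of the control share. A plain sum over all rows and subtraction of a control share for each gene were added after the data were seen. For the share of a library the alternatives were the median over genes and omission of the 10 genes with most reads, with nuclear genes only added later.

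The fit was tested on simulated data, in which 200 genes of EpiLC minus ESC were changed 1.5-fold, 2-fold or 4-fold. For total counts 55.2%, 71.6% and 81.8% of them were recovered, for labelled counts 16.4%, 43.3% and 75.8%, and for labelled share 11.9%, 40.3% and 74.2%. False calls were 4.79%, 4.26% and 5.62% of all calls. Only 200 genes were changed, against 9102 that passed for total counts in the real EpiLC minus ESC, and counts were drawn from fitted count models. These rates therefore describe the simulated setting and not the power or false calls of the real comparisons. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.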

Results

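RNA made within 1 h and all poly(A) RNA were measured together in mouse cells at 3 steps of germ cell induction in culture. Embryonic stem cells (ESC, C57BL/6) were turned over 2 days into epiblast-like cells (EpiLC), which resemble the embryo's epiblast shortly after implantation, and these over 4 further days into primordial germ cell-like cells (PGCLC), which were sorted on the surface proteins ITGB3 and SSEA1. In SLAM-seq, cells take up 4-thiouridine (s4U), iodoacetamide (IAA) alkylates it in the RNA, and reads from newly made RNA then carry T-to-C changes. Cells received 400 µM s4U for 1 h, and libraries of transcript 3′ ends were sequenced, 3 for each cell type. A further 2 single libraries were made without IAA, 1 labelled as ESC and 1 labelled as a mixture of EpiLC and PGCLC.

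Each read was counted once for a gene, but reads in an interval shared by genes can count for each of them. Counted in this way, total reads were 39758001, 35433844 and 38607676 in ESC replicates 1, 2 and 3. They were 35997990, 36300929 and 37696736 in EpiLC and 33683060, 36041110 and 33122963 in PGCLC. The controls without IAA held 29665565 and 29143227 reads. Labelled reads, those counted by the authors as newly transcribed, came to 5996977, 5381973 and 6031456 in ESC, 4301081, 4207774 and 4576817 in EpiLC, and 2976135, 3274177 and 2938239 in PGCLC.

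The labelled share of all reads set the scale for every comparison of labelled RNA. It was 15.3% ± 0.286 in ESC, 11.9% ± 0.279 in EpiLC and 8.93% ± 0.135 in PGCLC (SD, n = 3), and 0.854% and 0.886% in the 2 controls (Wilson 95% intervals 0.851% to 0.857% and 0.882% to 0.889%, counting error only). Each pair of groups was fully separated, with a two-sided exact permutation p of 0.1 for all 3 pairs, which is the smallest p that 3 libraries against 3 can give. Transcripts of the nuclear genome followed the same order, at 15.3% ± 0.277, 11.6% ± 0.280 and 8.67% ± 0.128. Mitochondrial transcripts did not: their labelled share was 13.9% ± 0.482 in ESC, 26.9% ± 0.193 in EpiLC and 18.6% ± 0.307 in PGCLC, against 2.02% and 2.04% in the controls. mt-Co1, which encodes a subunit of cytochrome c oxidase, stood at 9.997% ± 0.0975, 19.3% ± 0.201 and 12.9% ± 0.155, and mt-Nd1, a subunit of complex I, at 21.8% ± 0.556, 41.7% ± 0.104 and 34.9% ± 0.904. Of 9 mitochondrial transcripts with at least 200 reads in each library, 9 were higher in all EpiLC libraries than in all ESC libraries and 8 were higher in all PGCLC libraries than in all ESC libraries.

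**Figure D1:**
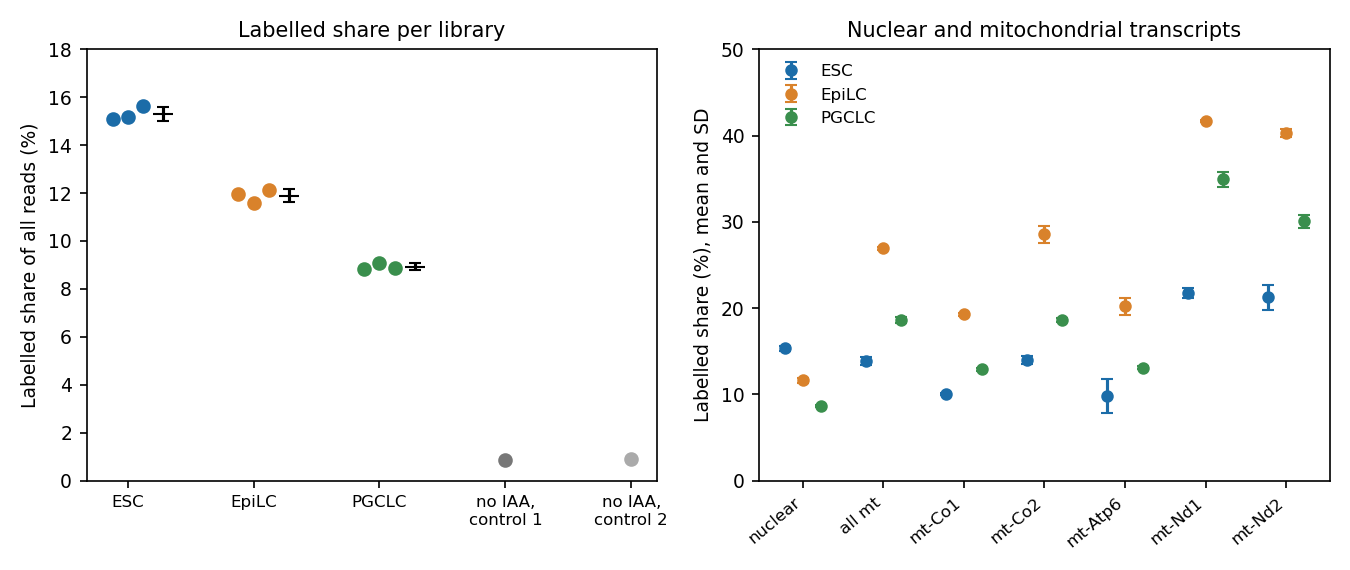
Left, labelled share of all reads (%) in each library, with the mean and SD of each cell type beside the points and the 2 controls without IAA as single points. Right, mean and SD (n = 3) of the labelled share of nuclear genes, of all mitochondrial genes and of 5 mitochondrial transcripts by cell type. The share of all reads falls from 15.3% to 8.93%, while that of mitochondrial transcripts is highest in EpiLC at 26.9%.

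The first comparison, EpiLC minus ESC, asked which transcripts changed as ESC left the naive state of the embryo before implantation. Genes of naive pluripotency fell and genes of the formative epiblast rose. Nanog, a homeobox factor of the pluripotency network, fell from 618 ± 36.6 CPM (counts per 1000000 reads of the library, mean ± SD, n = 3) in ESC to 35.7 ± 4.07 in EpiLC, a log2 difference of -4.11 with a standard error of 0.07 (adjusted p = 6.92e-22, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The self-renewal factors Klf4 and Esrrb fell from 1392 ± 40.8 and 562 ± 24.8 CPM to 41.4 ± 5.78 and 41.9 ± 1.18, and Zfp42 fell by 1.83 on the log2 scale. Sox2 fell by 1.42, from 726 ± 11.3 to 270.5 ± 11.5 CPM, whereas Pou5f1, its partner in the pluripotency network, did not pass the test (712 ± 44.7 and 686 ± 18.7 CPM, adjusted p = 0.317). The epiblast growth factor gene Fgf5 rose from 0.339 ± 0.214 to 59.5 ± 3.25 CPM. Pou3f1 and Otx2, transcription factors of formative cells, rose by 6.28 and 3.46, Pou3f1 reaching 1157 ± 62.6 CPM. Dnmt3b, which encodes a methyltransferase that sets new DNA methylation, rose from 91.8 ± 4.61 to 2844 ± 51.8 CPM (log2 difference 4.95, adjusted p = 5.10e-25), and the counts of this gene, ENSMUSG00000027478, came from a 3′ UTR interval on chromosome 2, 153686397 to 153687730 (GRCm38/mm10).

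Germ cell regulators that ESC already transcribed fell on the way to EpiLC. Tfap2c, a transcription factor of the early germline, fell from 90.5 ± 7.23 to 2.95 ± 1.05 CPM, and the transcriptional repressor genes Prdm1 and Prdm14 fell by 2.35 and 7.48 on the log2 scale. Dppa3, Nanos3 and the receptor gene Kit fell by 2.16, 2.35 and 3.39. Itgb3, the gene of the surface protein later used for sorting, stayed near the lower end of detection, at 0.561 ± 0.300 and 0.422 ± 0.305 CPM (adjusted p = 0.439). The mesoderm gene T fell from 21 ± 1.05 to 0.461 ± 0.324 CPM. By size of change among genes that reached 10 CPM, Enpp2, Car4, Gadd45g, Wt1, Tmem54 and Mmp25 rose most, by 7.66 to 8.34 on the log2 scale. Sp5, Cdx1 and Trpm1 fell, at log2 differences of -9.52, -8.37 and -8.19. S1pr1, Osm and Dmgdh were also among the 6 largest falls but held only 1, 3 and 3 reads over the EpiLC group, so that their ratios were 1535-fold, 559.9-fold and 369.7-fold with 95% counting intervals of 275 to 60672, 191 to 2718 and 126 to 1795.

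Among gene lists fixed before the data were examined, all 15 naive pluripotency genes tested fell, 15 adjusted over the list alone, with a median log2 difference of -3.11 (camera adjusted p = 9.19e-17). Adjustment over a list alone gave the same counts wherever no other counts are printed. Tfcp2l1 and Tbx3 were among these naive genes, at 1103 ± 21.4 and 482 ± 13 CPM in ESC and 11 ± 1.76 and 14.9 ± 0.628 in EpiLC. Of 15 formative epiblast genes, 14 rose and 1 did not pass (14 adjusted over the list alone, median 3.46, camera adjusted p = 2.38e-13), Dnmt3a rising from 49.6 ± 3.28 to 1583 ± 31.8 CPM and the kinase gene Pim2 by 4.77. Cholesterol synthesis rose in 14 of 16 genes and fell in 1 (14 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 4.04e-07), with Lss up by 2.04 and Hmgcs1 down by 0.90. Proliferation genes rose modestly in 14 of 15 cases (14 adjusted over the list alone, median 0.39, camera adjusted p = 5.19e-06), among them the replication helicase gene Mcm2, up by 0.88, and the mitotic kinase gene Plk1, up by 0.71. These 4 lists also passed when the correlation between genes was estimated, with adjusted p of 0.00204, 0.00208, 0.00853 and 0.0169.

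A further 5 lists passed camera with its preset correlation but not with an estimated one. Glycolysis genes rose in 9 of 13 cases and fell in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00115, adjusted p = 0.141 with an estimated correlation), and Ldha, which makes lactate, rose from 208 ± 17.7 to 1253 ± 15.5 CPM while Pkm rose by 1.23. Of 10 genes of the DNA methylation machinery, 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.00666, adjusted p = 0.0818 with an estimated correlation), with Dnmt3l up by 3.75 and the demethylation gene Tet2 down by 3.79. Exosome genes rose in 11 of 16 cases and fell in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.0818 with an estimated correlation), led by Exosc2, up by 1.35, and the nuclease gene Dis3, up by 0.92. The PGC specification list had 3 genes that rose and 11 that fell out of 15 (camera adjusted p = 0.0156, adjusted p = 0.0818 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 11 of 16 cases and rose in 2 (camera adjusted p = 0.0191, adjusted p = 0.0818 with an estimated correlation), and Cox5a fell by 0.72.

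The remaining lists did not pass camera in EpiLC minus ESC. Immediate-early genes rose in 10 of 15 cases and fell in 4 (10 and 5 adjusted over the list alone, camera adjusted p = 0.0867), Egr1 rising from 4.27 ± 1.28 to 161 ± 5.18 CPM. The counts of genes that rose and fell were 7 and 4 of 12 for shared pluripotency, 12 and 1 of 20 for later germline and meiosis, and 3 and 5 of 13 for mesoderm. They were 2 and 3 of 9 for BMP-SMAD targets, 2 and 0 of 9 for endoderm, 3 and 5 of 8 for trophoblast, and 4 and 1 of 8 for neurectoderm. For RNA decay they were 6 and 10 of 21 for deadenylation, where the antiproliferative genes Btg1 and Btg2 fell by 1.23 and 1.16, 7 and 4 of 15 for decapping and 5′ decay, and 5 and 6 of 14 for factors of nonsense-mediated decay (NMD; 6 and 6 adjusted over the list alone). NMD-sensitive transcripts gave 3 and 1 of 4, p53 targets 4 and 7 of 12, with Cdkn1a down by 1.61, and ribosomal proteins 2 and 6 of 20 (1 and 6 adjusted over the list alone). Of the NMD-sensitive list only Atf4, Ddit3, Gadd45a and Gadd45b were found, without Gas5 and the Snhg genes, so it says little about NMD. None of the 2-cell-like genes had enough reads to be tested. In all, 9102 of 14443 genes passed for total reads, 4449 higher and 4653 lower in EpiLC, of which 1897 and 2189 changed at least 2-fold.

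The marker genes also changed in newly made RNA. Of the 18 marker genes fixed beforehand, 6 were higher and 11 lower in labelled reads of EpiLC, relative to the typical gene, and Nanos3 did not pass (adjusted p = 0.0538). Itgb3 was counted as higher with 11 labelled reads over the EpiLC group, 0 of them in replicate 2, and none in ESC, so that it was at least 5.33-fold higher with 3 reads over the group as the floor, and its libraries were not separated. Labelled Nanog reads fell from 1389.6 ± 41 to 39.5 ± 5.96 labelled CPM and labelled Pou3f1 reads rose from 31.7 ± 1.35 to 3389 ± 352. Enpp2, which encodes a secreted lysophospholipase, rose with 3 labelled reads over the ESC group, a ratio of 617-fold with a counting interval of 211 to 2995. Jph4, Btbd17 and Galnt3 had no labelled read in ESC and were at least 176-fold, 127-fold and 109-fold higher in EpiLC with the same floor. Osm, Nkx1-2, S1pr1 and Emp1 had none in EpiLC and were at least 305-fold, 237-fold, 203-fold and 122-fold lower there. As lists in labelled reads, 15 of 15 naive pluripotency genes fell and 14 of 14 formative epiblast genes rose (camera adjusted p = 1.62e-19 and 8.88e-16). Of 16 cholesterol synthesis genes 13 rose (14 adjusted over the list alone, camera adjusted p = 3.17e-08). All 20 ribosomal protein genes rose (camera adjusted p = 6.32e-15), or 14 with 1 fall when the library sizes of the total reads were used. With an estimated correlation their adjusted p was 0.00129, or 0.00445 for cholesterol synthesis. Labelled reads passed for 4715 of 11339 genes, 2394 higher and 2321 lower. With the library sizes of the total reads, which leave the lower overall labelling of EpiLC in the data, the median gene lay at -0.46 and the split was 1314 higher to 4264 lower.

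The labelled share asked whether newly made RNA made up a different part of a gene's reads, relative to the typical gene of the same library. Immediate-early genes, which growth factors but also the handling and dissociation of cells switch on within minutes, stood out. The data do not separate these causes from each other or from the induction itself, which started from ESC grown in 2i and LIF. The share rose in 12 of 15 of them and fell in none (14 adjusted over the list alone, median 1.34, camera adjusted p = 1.49e-10, adjusted p = 0.00814 with an estimated correlation), and 8 still rose with the library sizes of the total reads. Egr1 rose from 32.9% ± 10.5 to 77.4% ± 1.08 of its reads (log2 difference 3.30, adjusted p = 1.67e-09), Fos from 59.98% ± 6.66 to 82.2% ± 2.07, and Fosb from 32.1% ± 7.64 to 70.6% ± 2.51. Ribosomal protein genes rose in 20 of 20 cases (20 adjusted over the list alone, median 0.85, camera adjusted p = 8.62e-15, adjusted p = 0.0880 with an estimated correlation), and in 14 with 1 fall when the library sizes of the total reads were used. Their median share was 4.67% ± 0.188 in ESC and 5.72% ± 0.234 in EpiLC, against 0.274% and 0.298% in the controls, and Rplp0 rose from 4.36% ± 0.278 to 5.90% ± 0.423. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, so their values are uncertain. p53 targets rose in 6 of 11 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.121 with an estimated correlation). Cdkn1a was among the rises, though the median of the p53 targets turned to -0.06 with the library sizes of the total reads. Formative epiblast genes rose in 5 of 14 cases (6 adjusted over the list alone, camera adjusted p = 0.00420, adjusted p = 0.0880 with an estimated correlation) and in 1 with 1 fall on that scale. Nuclear genes of oxidative phosphorylation rose in 7 of 16 (10 adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.121 with an estimated correlation), but their median of 0.41 turned to -0.12 on that scale.

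Single pluripotency factors parted in the same measure. Sox2 rose from 48.6% ± 0.220 to 59.5% ± 0.399 although its total level fell, and so did Klf4, from 41.1% ± 0.196 to 54.3% ± 3.66, and Klf2, from 56.7% ± 0.773 to 74.1% ± 1.94. Nanog fell from 36.6% ± 1.5 to 13.2% ± 1.94, Tet1 from 29.7% ± 1.25 to 13% ± 1.71 and Prdm1 from 49.6% ± 2.86 to 19.6% ± 6.10. The deadenylase gene Cnot8 fell from 38.2% ± 1.80 to 13.4% ± 3.48, while the decay factor genes Zfp36 and Zfp36l1 rose to 79.99% ± 5.03 and 60.03% ± 2.33. The largest fitted rises were in Dtx4, Mapk12, Olfr1152, Rprm, Ptprn and Slc27a2 and the largest fitted falls in Nkx1-2, Rab29, Parp3, Eps8l2, Lgals3 and Hesx1, all of them genes with few labelled reads in 1 of the groups. Hesx1 had 0 labelled reads of 125 in EpiLC, which allows a share of up to 2.40%, and 19.3% ± 1.75 in ESC. The share passed for 1895 of 11336 genes, 951 higher and 944 lower, and with the library sizes of the total reads the median gene lay at -0.53 and the split was 306 higher to 3680 lower. limma on median-centred log2 ratios called 600 higher and 377 lower.

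The second comparison, PGCLC minus EpiLC, asked which transcripts changed as EpiLC were induced to the germ cell fate. A sort is named for PGCLC alone, so its handling and selection cannot be told apart from the induction here. That holds also for immediate-early genes and for the labelled share. Genes of PGC specification rose in 15 of 15 cases and those of naive pluripotency in 14 of 15, while those of the formative epiblast fell in 13 of 15, with the tests given below. Prdm1 rose from 3.04 ± 0.659 CPM in EpiLC to 119 ± 11.1 in PGCLC (log2 difference 5.30, standard error 0.14, adjusted p = 1.59e-18), from an interval of ENSMUSG00000038151 on chromosome 10, 44437177 to 44439669. Tfap2c rose from 2.95 ± 1.05 to 488 ± 13.6 CPM and Prdm14 from 0.0580 ± 0.0502 to 21.3 ± 2.36. Dppa3, which encodes a chromatin protein of germ cells and early embryos, rose from 6.43 ± 0.438 to 249 ± 13, and the RNA-binding factor gene Nanos3 rose by 5.35 on the log2 scale. Kit rose by 3.41, and Itgb3, whose protein was part of the sort, rose from 0.422 ± 0.305 to 17.4 ± 3.16 CPM. Nanog, Esrrb, Klf4, Zfp42 and Sox2 rose by 3.44, 3.03, 2.19, 0.83 and 1.38, and Pou5f1 fell slightly, by 0.36. Fgf5, Otx2 and Pou3f1 fell by 4.40, 3.35 and 4.51. Dnmt3b fell from 2844 ± 51.8 to 40.2 ± 2.63 CPM, and T rose to 2.28 ± 0.567 CPM.

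**Figure D2:**
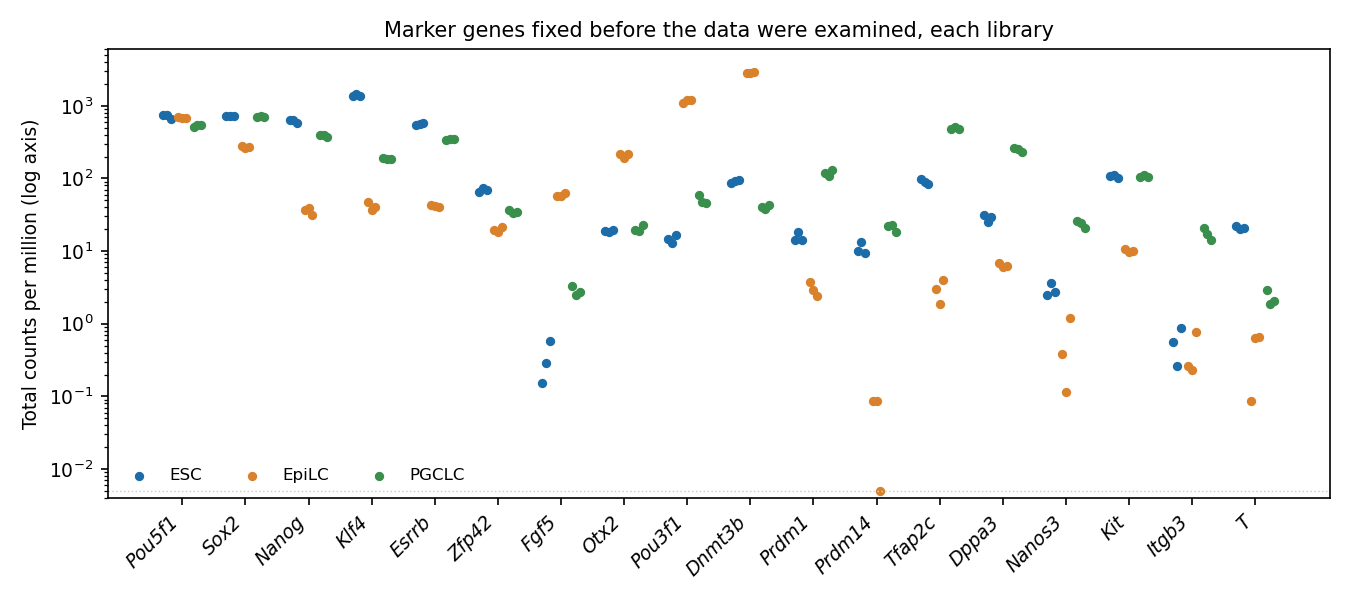
Total CPM of the 18 marker genes fixed before the data were examined, on a log axis, with 1 point for each library coloured by cell type. A library with 0 reads is drawn on the dotted line. Dnmt3b reaches 2844 CPM in EpiLC and Tfap2c reaches 488 CPM in PGCLC.

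Of the lists of other embryonic lineages, the trophoblast list rose in 7 of 8 genes and fell in 1 (7 and 1 adjusted over the list alone, median 5.24, camera adjusted p = 0.0111, adjusted p = 0.0615 with an estimated correlation). Hand1, a transcription factor of trophoblast and extraembryonic mesoderm, rose from 0.427 ± 0.128 to 97.3 ± 4.998 CPM, and Gata2 and Gata3 rose by 5.79 and 6.32. Mesoderm genes rose in 9 of 13 cases (9 adjusted over the list alone, median 2.13, camera adjusted p = 0.0714, adjusted p = 0.134 with an estimated correlation), among them Eomes, up by 3.06, and Wnt3, up by 3.38. Endoderm genes rose in 2 of 9 cases, and neurectoderm genes rose in 1 of 8 and fell in 4 (camera adjusted p = 0.672 and 0.387). Of the targets of BMP-SMAD signalling, the pathway whose ligand induces germ cells, 9 of 9 rose (9 adjusted over the list alone, median 2.39, camera adjusted p = 8.13e-06, adjusted p = 0.0131 with an estimated correlation), with Id1 rising from 1.76 ± 0.360 to 71.7 ± 1.23 CPM, Id3 by 2.16 and Msx2 by 6.72. By size, Rbms3 and Rgs5 rose from 3 and 2 reads over the EpiLC group, ratios of 801-fold and 666-fold with counting intervals of 274 to 3888 and 184 to 5503, and BC048679 rose by 9.22 on the log2 scale. Igf2 also rose, by 7.82, but all of its reads lay in an interval shared with the gene model Gm49394 and are uncertain. Jph4, Dcn and Cdk5r2 fell, with log2 differences from -6.84 to -6.07.

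PGC specification genes rose in 15 of 15 cases (15 adjusted over the list alone, median 5.27, camera adjusted p = 3.54e-11), Ifitm1 reaching 1262 ± 4.29 CPM, in libraries where 7 of 8 trophoblast and 9 of 13 mesoderm genes were also higher. Naive pluripotency genes rose in 14 of 15 and fell in 1 (14 and 1 adjusted over the list alone, median 2.499, camera adjusted p = 3.54e-11), Klf2 and Tfcp2l1 by 2.499 and 4.13. Formative epiblast genes fell in 13 of 15 and rose in 1, Krt18, named after its value was seen (13 and 1 adjusted over the list alone, median -2.78, camera adjusted p = 5.45e-11). Cholesterol synthesis genes fell in 15 of 16 and rose in 1 (15 and 1 adjusted over the list alone, median -1.58, camera adjusted p = 3.54e-11), with Cyp51 and Msmo1 down by 1.89 and 1.57. Glycolysis genes fell in 11 of 13 and rose in 2 (11 and 2 adjusted over the list alone, median -0.9986, camera adjusted p = 1.16e-06), Ldha falling to 155 ± 15 CPM. Proliferation genes fell in 13 of 15 and rose in 1 (13 and 1 adjusted over the list alone, median -0.49, camera adjusted p = 1.16e-06), Mcm2 and Plk1 by 1.000 and 1.095. In the DNA methylation machinery 6 of 10 genes fell and 2 rose (camera adjusted p = 0.00317). Uhrf1, which keeps methylation through cell division, fell from 301 ± 10.4 to 64.1 ± 3.83 CPM while Dnmt3a fell by 5.01. These 7 lists passed with an estimated correlation too, at adjusted p of 0.00197 for the first 4 named, 0.0447 for glycolysis, 0.0117 for proliferation and 0.0447 for DNA methylation.

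p53 targets fell in 9 of 12 and rose in 2 (camera adjusted p = 0.0108, adjusted p = 0.0603 with an estimated correlation), with Pmaip1 down by 2.07. Exosome genes fell in 10 of 16 and rose in 2 (camera adjusted p = 0.0164, adjusted p = 0.0856 with an estimated correlation), with Exosc2 down by 1.33. Immediate-early genes split into 6 that rose, among them Jun and Junb at 2.77 and 2.71, and 8 that fell, among them Egr1 at -3.02 (6 and 9 adjusted over the list alone, camera adjusted p = 0.789). Later germline genes rose in 7 of 20 and fell in 3 (camera adjusted p = 0.527, adjusted p = 0.606 with an estimated correlation), and Dmrt1 rose by 2.42. In all, 8853 of 14443 genes passed for total reads, 4651 higher and 4202 lower in PGCLC, of which 2262 and 1508 changed at least 2-fold.

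In labelled reads 12 of the 18 marker genes were higher in PGCLC and 5 lower, and T did not pass (adjusted p = 0.973). Labelled Prdm1 reads rose from 4.78 ± 0.441 to 579 ± 83.5 labelled CPM, and labelled Dppa3 reads from 0.646 ± 0.506 to 300.4 ± 0.929. Prdm14 had no labelled read in EpiLC and was at least 219.7-fold higher in PGCLC, and Tinagl1, Hand1 and Thsd4 were at least 135-fold, 124-fold and 102-fold higher, with 3 reads over the group as the floor. Cdk5r2 and Rims4 had none in PGCLC and were at least 104-fold and 84.6-fold lower there. As lists in labelled reads, 14 of 15 PGC specification genes rose and 13 of 14 formative epiblast genes fell (camera adjusted p = 2.96e-13 for both, adjusted p = 0.00203 with an estimated correlation). Falls were also seen in 14 of 16 cholesterol synthesis genes and 17 of 20 ribosomal protein genes (camera adjusted p = 5.01e-10 and 3.55e-09, adjusted p = 0.00244 with an estimated correlation). Labelled reads passed for 4537 of 11339 genes, 2276 higher and 2261 lower, and with the library sizes of the total reads the median gene lay at -0.52 and the split was 1261 to 4495.

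The labelled share turned the other way for several genes of the first step. It fell in 9 of 15 immediate-early genes and rose in none (10 adjusted over the list alone, median -1.31, camera adjusted p = 3.40e-06, adjusted p = 0.0317 with an estimated correlation), with Egr1 at 32.9% ± 5.42 and Fos at 50.7% ± 1.39 of their reads in PGCLC. Ribosomal protein genes fell in 15 of 20 cases and rose in 1 (16 and 1 adjusted over the list alone, median -0.50, camera adjusted p = 3.40e-06, adjusted p = 0.200 with an estimated correlation), to a median share of 2.87% ± 0.141. BMP-SMAD targets, whose total level rose, fell in share in 4 of 8 cases (camera adjusted p = 0.00517, adjusted p = 0.121 with an estimated correlation), Id3 from 52.5% ± 3.33 to 17.9% ± 0.464. p53 targets fell in 6 of 11 and rose in none (6 and 1 adjusted over the list alone, camera adjusted p = 0.0169, adjusted p = 0.130 with an estimated correlation), Mdm2 from 45.3% ± 3.71 to 21.7% ± 1.71. PGC specification genes rose in 6 of 15 cases (camera adjusted p = 0.0105, adjusted p = 0.121 with an estimated correlation), and in 4 with 2 falls on the library sizes of the total reads, Prdm1 going from 19.6% ± 6.10 to 40.4% ± 1.36 and Dppa3 from 1.17% ± 0.857 to 10.1% ± 0.532. Nanog rose to 20.9% ± 1.37 and Tfcp2l1 from 7.31% ± 2.18 to 14.8% ± 1.12, while Sox2 fell to 22.7% ± 0.259, Klf2 to 30.7% ± 0.405 and Tbx3 from 46.5% ± 3.91 to 13% ± 1.71. Beside Dppa3, the largest fitted rises were in Rbm46, Eps8l2, Lgals3, Mok and Traf5, which had 0 to 3 labelled reads over the EpiLC group, and the largest fitted falls in Rab20, Tex19.2, Zfp239, Mef2b, Armcx6 and Fam13c, which had 0 labelled reads in PGCLC. The sizes and order of these changes are uncertain, and for Zfp239 the fall itself. Its 0 labelled reads of 254 in PGCLC allow up to 1.18%, below its 5.33% (17 of 319 reads) in the 2 controls together. The share passed for 1778 of 11336 genes, 930 higher and 848 lower, and with the library sizes of the total reads the median gene lay at -0.62 and the split was 185 to 3962.

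**Figure D3:**
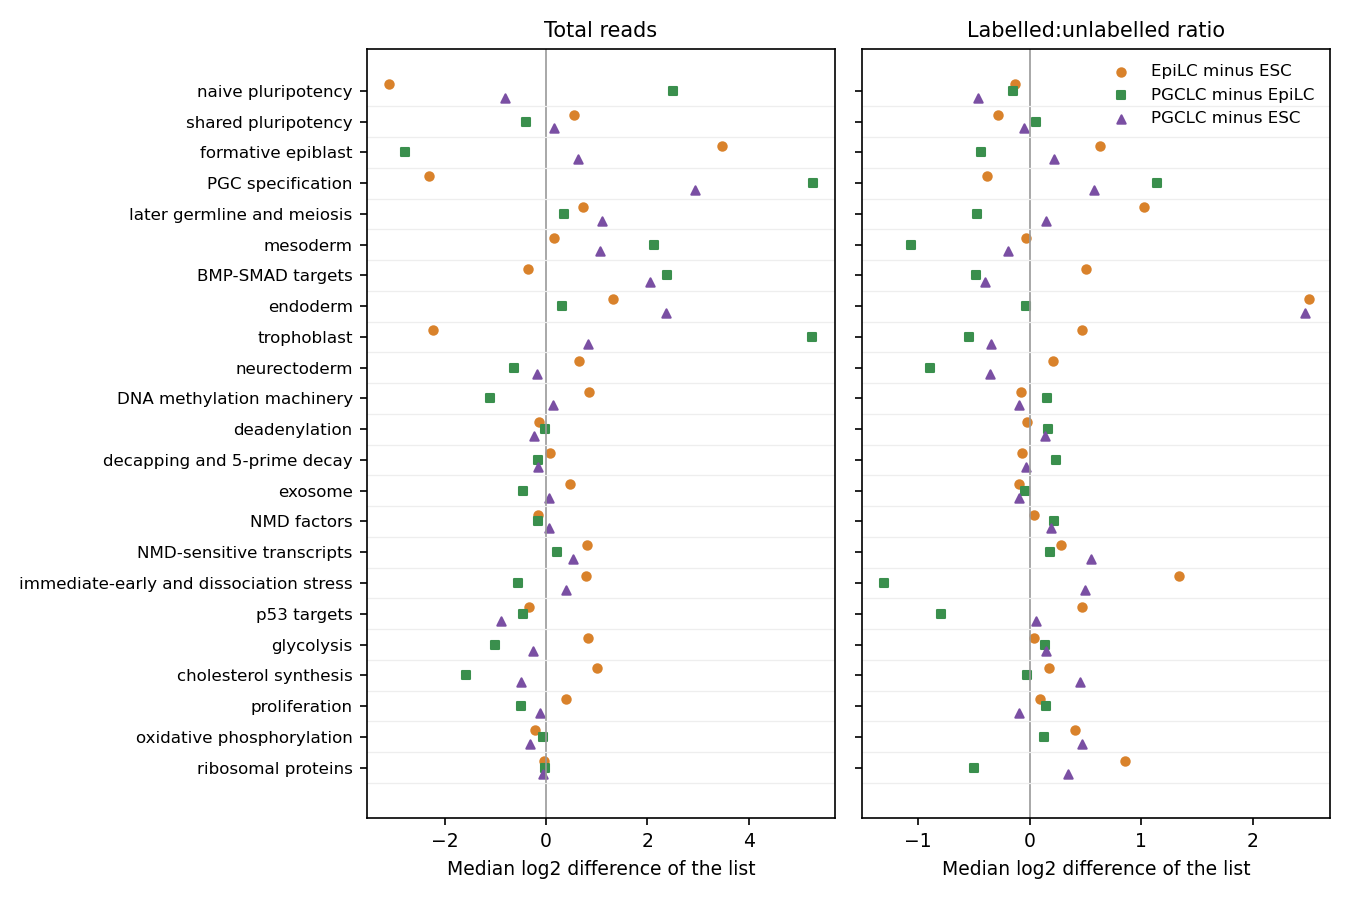
Median log2 difference of each gene list with tested members, for total reads on the left and for the labelled to unlabelled ratio relative to the typical gene on the right, with 1 symbol for each comparison. The PGC specification list has the highest total median in PGCLC minus EpiLC at 5.27. Its ratio median of 0.58 in PGCLC minus ESC turns to -0.54 with the library sizes of the total reads, as does that of the ribosomal proteins, from 0.35 to -0.77.

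The third comparison, PGCLC minus ESC, asked how germ cell-like cells differed from the stem cells they came from. The sort of PGCLC cannot be told apart from cell type in this comparison either. Genes of PGC specification were higher in 14 of 15 cases and those of naive pluripotency lower in 13 of 15, with the tests given below. Dppa3, Tfap2c, Prdm1 and Nanos3 were higher in PGCLC by 3.12, 2.43, 2.94 and 3.001, Itgb3 by 4.93 and Prdm14 by 0.98. Sox2, Otx2 and Kit did not pass (adjusted p = 0.327, 0.261 and 0.832), Kit standing at 106 ± 4.90 and 108 ± 3.8 CPM. Nanog, Esrrb, Zfp42 and Pou5f1 were lower by 0.68, 0.71, 0.99 and 0.42, and Klf4 by 2.88. Dnmt3b and T were lower, at -1.19 and -3.20, and Fgf5 and Pou3f1 remained higher by 3.05 and 1.77. Hand1 had the largest fitted rise among all genes that met the naming rule, by 10.74, from 6 reads over the ESC group. Creb5 and Rgs5 rose from 3 reads each over the ESC group, ratios of 475-fold and 473-fold with counting intervals of 162 to 2308 and 162 to 2296, and Plac1, Vsir and BC048679 rose by 7.97, 7.90 and 7.66. Plac1 and Vsir had 5 reads each over the ESC group, so the sizes and order of these rises are uncertain. The largest falls were in Vwf, Cd3d, Ppp1r14d, Gpx2, Adh1 and Nkx6-2, by 6.37 to 8.31, where Vwf and Cd3d held 8 and 5 reads over the PGCLC group.

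PGC specification genes were higher in 14 of 15 cases (14 adjusted over the list alone, median 2.94, camera adjusted p = 1.79e-12), Rhox9 and Dnd1 by 4.29 and 3.87. BMP-SMAD targets were higher in 8 of 9 (8 adjusted over the list alone, median 2.05, camera adjusted p = 3.28e-06), beside 5 of 8 trophoblast genes that rose and 2 that fell (camera adjusted p = 0.282). Naive pluripotency genes were lower in 13 of 15 and higher in 1 (13 and 2 adjusted over the list alone, median -0.81, camera adjusted p = 3.08e-10), Jam2 and Fgf4 by 3.78 and 2.62. Cholesterol synthesis was lower in 12 of 16 and higher in 1, and oxidative phosphorylation lower in 14 of 16 and higher in 1 (camera adjusted p = 0.000196 for both), with Uqcrc1 down by 0.51. p53 targets were lower in 8 of 12 and higher in 3 (8 and 4 adjusted over the list alone, camera adjusted p = 0.00178), Cdkn1a falling from 602 ± 43.4 to 136 ± 8.01 CPM. With an estimated correlation these 6 lists had adjusted p of 0.00444 for PGC specification and naive pluripotency, 0.0207 for BMP-SMAD targets, 0.0213 for cholesterol synthesis and oxidative phosphorylation, and 0.0392 for p53 targets. Formative epiblast genes were higher in 9 of 15 and lower in 3 (camera adjusted p = 0.0391, adjusted p = 0.119 with an estimated correlation), and Krt18 rose by 4.48. Later germline genes were higher in 11 of 20 and lower in 1 (camera adjusted p = 0.0391, adjusted p = 0.183 with an estimated correlation), with Dazl and Ddx4 up by 1.56 and 1.66. Immediate-early genes were higher in 7 of 15 and lower in 2 (camera adjusted p = 0.0283, adjusted p = 0.102 with an estimated correlation), Fos rising by 2.48. In all, 8202 of 14443 genes passed, 4138 higher and 4064 lower in PGCLC, of which 1967 and 1466 changed at least 2-fold.

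In labelled reads 14 of 15 PGC specification genes were higher and 11 of 15 naive pluripotency genes lower (14 and 1, and 1 and 11, higher and lower adjusted over the list alone, camera adjusted p = 1.91e-13 and 5.73e-12, adjusted p = 0.00284 with an estimated correlation). Labelled reads of PGCLC and ESC differed in 4418 of 11339 genes, 2229 higher and 2189 lower, and with the library sizes of the total reads the median gene lay at -0.98 and the split was 783 to 6924. Rgs16 rose from 1 labelled read over the ESC group, a ratio of 2404-fold with a counting interval of 431 to 95044, and Creb5, Chdh and Rflna had none there and were at least 257-fold, 156-fold and 150.2-fold higher. Accsl, Fam198b, Kdelr3 and Pdzrn4 had none in PGCLC and were at least 115-fold, 106-fold, 80.9-fold and 63.7-fold lower. The labelled share passed for 1973 of 11336 genes, 1031 higher and 942 lower, and with the library sizes of the total reads the median gene lay at -1.16 and the split was 76 to 7566. Only changes of the same sign on both scales are named next. Cldn6, a tight junction gene, rose from 6.45% ± 0.894 to 11.3% ± 1.18 of its reads. Prdm14 rose from 9.96% ± 4.32 to 20.5% ± 1.97. Sox2 fell from 48.6% ± 0.220 to 22.7% ± 0.259, Mdm2 from 55.4% ± 0.770 to 21.7% ± 1.71, and Olig2 from 62.3% ± 0.306 to 23.8% ± 1.25. The largest fitted rises were in Sct, Cx3cl1, Itgb3, Wnt4, Rgs16 and Traf5, with 0 to 2 labelled reads over the ESC group, so that their sizes and order are uncertain. In ESC Sct had 0 labelled reads of 125, Itgb3 0 of 64 and Wnt4 0 of 52, which allows up to 2.40%, 4.69% and 5.77%, against 5.88%, 6.42% and 5.95% of all reads in PGCLC. Rgs16 had 1 of 14 in ESC and its libraries were not separated, and Itgb3 did not pass with the library sizes of the total reads. The largest fitted falls were in Kdelr3, Apobr, Tgm1, Cmklr1, Fam13c and Bdkrb2, which had 0 labelled reads in PGCLC, a limit of 0.370% for Kdelr3 to 3.95% for Fam13c, against 11.02% and 33.6% of all reads in ESC. For Kdelr3 alone this limit lay below the share in the 2 controls together, 2.23% (35 of 1571 reads). Its falls in labelled reads and in share are therefore uncertain. Of the gene lists 5 passed camera in this share with its preset correlation and none with an estimated one, where the lowest adjusted p was 0.235.

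In all 3 comparisons p-values measured the spread between replicates whose independence the labels do not state.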

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

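The tests of a mixture, of ESC RNA under another label, of background conversions, of labelling efficiency and of scaling were chosen after the results were seen. A signal was found in a library that no comparison used: the total counts of the library labelled as EpiLC plus PGCLC without iodoacetamide correlated with those of ESC libraries at 0.990 on average, against 0.909 with EpiLC and 0.925 with PGCLC. In the 2 libraries without iodoacetamide together, 99 of 10288 genes with at least 200 reads had a labelled share over 5%, and Dnajc25 had the highest at 27.2%.

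The library labelled as EpiLC plus PGCLC without iodoacetamide looked like ESC. A mixture of the 2 labelled types was argued against by fitted weights of EpiLC and PGCLC that summed to 0.0374, while ESC had 0.962. It was also argued against by 0.309 CPM of Fgf5 where the lower of the 2 types had 3.002, both computed without TMM factors. Deposition of 1 library under 2 names was argued against by a chi-square of 6.27 per degree of freedom between the controls. That value was below those of all pairs of replicates, 9.61 to 18.7, while controls against ESC libraries gave 54.2 to 69.6. Whether the 2 controls came from 1 RNA or preparation was not tested. RNA of ESC under another label had the values it needs: 93.0% of 1786 genes that set ESC apart from both other types lay nearer to ESC, against 93.3% for the control labelled as ESC. The background of EpiLC and PGCLC was therefore not measured in their own RNA, and no biological explanation was tested.

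The overall labelled share fell from ESC to EpiLC to PGCLC, while that of mitochondrial transcripts was higher in EpiLC and PGCLC than in ESC. Background conversions in ESC were argued against, since 86.6% of the fall from ESC to PGCLC was kept with the control share taken off ESC and nothing off PGCLC. A change in which genes make up the RNA was argued against as the main cause, since with every gene weighted as in ESC 99.97% of the fall to PGCLC and 80.6% of the fall to EpiLC were kept, so that part of the step to EpiLC went with composition. From ESC to EpiLC, mitochondrial transcripts argued against a lower labelling efficiency in all transcripts alike as the only cause. Their median log2 ratio of labelled to unlabelled reads rose by 1.299. The test cannot exclude such an efficiency beside an opposite change in mitochondrial transcripts, because no added labelled RNA is named. That test did not cover the step to PGCLC, where 8 of 9 mitochondrial transcripts were lower in all PGCLC than in all EpiLC libraries. There the mitochondrial share fell from 26.9% to 18.6% and the nuclear share from 11.6% to 8.67%. A lower efficiency in all transcripts alike therefore stays open for that step, also as the only cause. For nuclear transcripts alone the median from ESC to EpiLC was -0.54, with 2331 of 11011 genes above 0. The differences of single genes had an SD of 0.869, 1.496 times the 0.581 expected from the spread of replicates. This spread cannot decide on a lower efficiency in nuclear transcripts, because a common efficiency moves the log2 ratio more in genes with a high share. Such an efficiency cannot be told apart from slower renewal of nuclear RNA, an untested biological explanation, because the labels name no added labelled RNA. For PGCLC, the sort named for these cells alone cannot be told apart from cell type as a source of the fall.

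Relative to the typical gene, ribosomal protein transcripts had a higher labelled share in EpiLC than in ESC in 20 of 20 genes. Their mean share in percent of reads was higher in 19 of 20. As a list they did not pass camera with an estimated correlation (adjusted p = 0.0880). The scaling of labelled reads was argued against by a median of 0.32 with the library sizes of the total reads. A shift of abundant transcripts in general was argued against because the central 95% of the medians of 10000 random lists matched on read number, which leave out the correlation between genes, ended at 0.31, against 0.85 for the list. Background conversions cannot be told apart from labelling as the source of the rise of 1.06 percentage points in the median share, because no control had EpiLC RNA. Reads shared with pseudogenes, which were not tested, and a biological difference between the cell types also stay open.

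For every comparison of groups the 6 libraries made 10 splits, which are too few for a share under 0.05. Any split but the real split mixes both cell types in each group, which by construction raises the spread within groups. The low counts of such splits therefore cannot speak against chance. The real split was the only 1 as large in each case. For total reads it called 8919 genes in EpiLC minus ESC, 8866 in PGCLC minus EpiLC and 8164 in PGCLC minus ESC, for labelled reads 5115, 4189 and 4289, and for labelled share 2281, 1571 and 1970.0, and the highest other split called 0 in all 9.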

How the results depend on the processing

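The plain sum over all rows, the subtraction of a control share for each gene and the share of nuclear genes only were chosen after seeing the data, and the cause of the changes below was not tested unless named. With a change of at least 2-fold required, which by construction lowers the number, 4086, 3770.0 and 3433 genes passed for total reads in EpiLC minus ESC, PGCLC minus EpiLC and PGCLC minus ESC. For labelled reads these numbers were 2919, 2735 and 2697, and for labelled share 716, 706 and 768. With the library sizes of the total reads, which leave the overall difference in labelling in the data, 7707 genes passed for labelled reads in PGCLC minus ESC, and 3986, 4147 and 7642 for labelled share. limma on log2 ratios called 977, 930.0 and 1014 for labelled share. As the median over genes, the share of a library differed by -5.52, -3.57 and -9.08 percentage points, and without the 10 genes with most reads by -3.85 in EpiLC minus ESC and -6.83 in PGCLC minus ESC.

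With an estimated correlation 4 of 9 gene lists passed for total reads in EpiLC minus ESC, and for labelled reads 6 of 11, 8 of 13 and 5 of 8. For labelled share 1 of 5 passed in EpiLC minus ESC, 1 of 5 in PGCLC minus EpiLC and 0 of 5 in PGCLC minus ESC. With the library sizes of the total reads the median labelled share of 4 lists changed sign. It was -0.059 for p53 targets and -0.12 for oxidative phosphorylation in EpiLC minus ESC, and -0.77 for ribosomal proteins and -0.54 for PGC specification in PGCLC minus ESC.

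With the replicate number as a replicate block, 4559, 4384 and 4231 genes passed for labelled reads and 1759, 1695 and 1854 for labelled share. Residuals of libraries with the same number in different groups had correlations from -0.0635 to 0.0482, and 0 of 9 were above 0.1, so the numbers gave no sign of pairing.

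Leaving out each library in turn gave 8558 to 9136, 8291 to 9027 and 7580.0 to 8344 genes for total reads. It gave 4140.0 to 5023, 3972 to 4519 and 3754 to 4516 for labelled reads, and 1325 to 2001, 1384 to 1676 and 1382 to 1960.0 for labelled share. The share of a library then differed by -3.53 to -3.24, -3.11 to -2.84 and -6.48 to -6.21 percentage points. No named gene lost its call in total reads. In labelled reads Itgb3 in EpiLC minus ESC did without EpiLC replicate 3, at 3.81 (adjusted p = 0.0925), and in labelled share 16 of 65 did in at least 1 omission, all of them genes with few labelled reads in 1 group, most often without ESC replicate 3, with 10 calls. Of the genes that had not passed in EpiLC minus ESC, Nanos3 in labelled reads and Itgb3 in total reads passed without EpiLC replicate 3, at -3.95 and -1.18, and Pou5f1 in total reads without ESC replicate 3, at -0.11.

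In the other alternatives no named gene changed direction. Nanos3 in labelled reads of EpiLC minus ESC passed with no filter, with the stricter filter, with DESeq2 and with the library sizes of the total reads, at -2.24, -2.22, -2.29 and -2.67. Named changes in total reads all kept their call, and in labelled reads all but Itgb3 in EpiLC minus ESC with limma voom, at 2.87 (adjusted p = 0.125), which had too few reads to be tested with only the 2 groups compared. Of 65 in labelled share only 58 passed the stricter filter and were tested with it, and none of these lost its call. Under each of the other alternatives between 0 and 6 of 65 lost it, the share of Itgb3 in PGCLC minus ESC among them, at 3.49 (adjusted p = 0.0508) with the library sizes of the total reads.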

Other observations

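Mitochondrial transcripts held 2.40% of reads in ESC, 1.87% in EpiLC and 2.64% in PGCLC. Transcripts of some genes carried T-to-C reads without iodoacetamide, among them Gdf15 with 11.4% of 1952 reads. No hypothesis beyond these values was tested.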
